A study of Mus musculus with 8 samples.

How the data were processed

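Messenger RNA was measured in pieces of kidney cortex from male mice of 2 related inbred strains. SAMP1 is a senescence-prone strain and SAMR1 is its senescence-resistant counterpart. Each strain was sampled at 10 weeks and at 50 weeks of age, with 2 mice per group, 1 array per mouse and 8 arrays in all. Per the labels, RNA came from 10 mg of tissue and 50 ng of it was labelled with the dye Cy3 for a 1-colour Agilent mouse array with 60-base probes.

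The spot intensity values were deposited as scanner output made with Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes. Per the file headers, the processed intensity of each spot was background-subtracted and corrected for spatial and multiplicative trends within its array, and it was not normalized between arrays. The mean spot intensity and the local background intensity were deposited without further correction, per the file headers. The deposited flag columns hold yes-or-no marks for outlier spots, saturation and being well above background, and they were used as given per the file headers. The authors also deposited a value table on a log2 scale for the same 8 arrays, and no source used here states how it was made. Set against the scanner values, each of its columns matched log2 processed intensity minus the array's 75th percentile, centred per probe on the median over the 8 arrays, with a correlation of 0.99993 to 0.99997. The column medians ran from -0.048 to 0.0591. Direction, scale and centring of that table were settled by this comparison, and it served only as an alternative. Because of the centring it holds differences between arrays and no levels.

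Each array carried 59305 spots for 56605 probes that were not controls. From 102 to 161 spots per array were marked as outliers and left out, and none was saturated. The arrays lay on 1 slide and were read in 1 scan, so slide and scan were not batches. Both slide rows held arrays of all 4 groups. Slide columns 1 and 2 held the 10-week arrays and columns 3 and 4 the 50-week arrays, so age and slide column cannot be told apart by design.

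For the analysis, log2 of the processed intensity minus the array's 75th percentile over all probes that were not controls was taken for each spot, and spots of 1 probe were averaged. Of the 56605 probes, 35405 were matched by accession to a table of mouse gene names of the GRCm38.p6 assembly, 1 of them received a newer name, and 21200 kept the name in the file. Probe coordinates are on mm9, per the file headers, and whether a probe lies in an exon or UTR was not analysed here because no genome of that build was used. Strain variants under the probes were not looked up for the same reason. A probe was kept where it was well above background on both arrays of at least 1 group. Among 36610 gene names, each gene was represented by its probe with the highest mean over the 8 arrays. In all, 5 probes were dropped for outlier marks, 35375 probes were kept and 22646 genes were tested.

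Gene differences were tested 2-sided with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. All 8 arrays entered with a coefficient per group, and the fit shared 4 residual degrees of freedom and a prior of 2.36. The 5 contrasts were the age change in each strain (50 weeks minus 10 weeks), the strain difference at each age (SAMP1 minus SAMR1), and the age by strain interaction (SAMP1 age change minus SAMR1 age change). Adjusted p-values are Benjamini-Hochberg values over all genes tested, per contrast, with a threshold of 0.05. The number of arrays limits the precision of every estimate. The standard errors and adjusted p-values given for genes are from limma throughout.

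In all, 38 gene lists for kidney cell types, immune and other cell types, injury, ageing and metabolism were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 180 tests. A list needed at least 5 measured members, and 36 lists met that. The lists for adipocytes and for the adrenal gland had too few members. Each list was also tested with a correlation estimated from the data and with fry, a rotation test of whether the genes of a list move, on balance, one way. With the estimated correlation 0 of the 180 tests passed, and the smallest adjusted p was 0.485. With fry 8 passed, namely 2 for age in SAMP1, 0 for age in SAMR1, 2 and 3 for strain at 10 and 50 weeks and 1 for the interaction. At the preset correlation 64 passed, and 6 of these also passed with fry.

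Where a gene was not well above background on any array of a group, the fold is given as a bound in the form "at least N-fold". It sets the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. A log2 difference or standard error given beside such a bound is the fitted value, which depends on signals near background. No fold is given where both groups were not well above background. The genes named were the 10 highest and the 10 lowest log2 fold changes among genes that passed in each contrast, leaving out names that are only clone, locus or accession names. Where no such gene passed, the 5 higher and 5 lower genes with the smallest p are named and said not to pass. Up to 4 members with the smallest p of each list described, and 5 genes that check the labels, were also named. A few genes that this rule picks are not reported here, but they stay in the lists and in the counts of lists and of the 20 largest changes. The groups, the tests, the lists, this rule and the alternatives were chosen before the data were examined. Haemoglobin level as a covariate and leaving out immunoglobulin genes were chosen as alternatives after seeing the data.

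Immunoglobulin genes were taken as genes described as immunoglobulin heavy, kappa or lambda genes, or with such symbols, and 149 were tested. Overlaps were compared with the number given by independent lists and tested with Fisher's exact test. The alternatives covered quantile and median scaling, normexp background correction with an offset of 50, the filter on dim probes, the choice of probe, the slide row as a block, the groups in the fit, the spread model, the thresholds, the deposited value table, and each array left out in turn.

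The steps were tested on simulated data with 22646 genes, of which 200 were changed, 50 at each fold. For the age change in SAMP1, 6% of genes changed 1.5-fold, 48% of those changed 2-fold, 96% of those changed 4-fold and 100% of those changed 16-fold were recovered, with 12 false calls. For the age change in SAMR1 the shares were 10%, 64%, 84% and 98%, with 3 false calls. For the strain difference at 10 weeks they were 8%, 66%, 94% and 100%, with 6 false calls, and at 50 weeks 10%, 66%, 96% and 100%, with 7 false calls. For the interaction they were 0%, 26%, 76% and 100%, with 6 false calls. A simulated list of 20 genes shifted by 1 log2 unit was called in each of the 5 contrasts, and 0 of the other lists was. Genes were simulated with independent noise and the lists drawn at random. The simulation therefore cannot show how often lists whose members vary together are called falsely. Other tools were version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.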

Results

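Gene expression in kidney cortex was compared between SAMP1 mice, which age prematurely, and SAMR1 mice, their resistant control, at 10 and 50 weeks. The series concerns messenger RNA changes in renal impairment that comes with age. On the 8 arrays, 61.4% to 64.4% of spots were well above background, the median processed signal was 15.3 to 19.4 and the 75th percentile was 188 to 237. Arrays of a group correlated across genes at r = 0.9933 to 0.995 and arrays of different groups at r = 0.9743 to 0.9873, where genes are not independent replicates, and no arrays held identical values. Xist, which marks female tissue, was well above background on 0 arrays, while the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were well above background on 8 of 8. Levels are given as log2 signal relative to the array's 75th percentile, changes as log2 differences with the standard error from limma, and each group mean rests on n = 2 mice.

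The first comparison was age in SAMP1, where the highest rises at 50 weeks were in genes of antibody-producing cells. Iglv1, an immunoglobulin lambda variable gene, rose by 6.03 ± 0.711 and at least 32.2-fold (adjusted p = 0.0188). Jchain, which joins the units of polymeric antibodies, rose by 5.94 ± 0.645 from a mean of -2.96 to 2.98 (adjusted p = 0.0159). The heavy chain gene Igh-VJ558 rose by 5.08 ± 0.476 (adjusted p = 0.0108), the B cell surface gene Ms4a1 by 4.69 ± 0.443 and at least 13.6-fold (adjusted p = 0.0108), and Pou2af1, a transcriptional coactivator of B cells, by 3.16 ± 0.246 and at least 8.09-fold (adjusted p = 0.00569). Slpi, an inhibitor of leukocyte proteases, rose by 3.74 ± 0.437 (adjusted p = 0.0185), and the inducible chaperone gene Hspa1b rose 7.2-fold (2.85 ± 0.285, adjusted p = 0.0137). Mmp3, a matrix metalloproteinase, rose at least 5.34-fold, and the transcription factor genes Neurog2 and Lhx2 rose at least 6.49-fold and at least 2.97-fold. Age changes were not compared probe by probe, and another Ms4a1 probe lacked the strain difference at 50 weeks.

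Among genes lower at 50 weeks in SAMP1, Serpina6, which encodes corticosteroid-binding globulin, was at least 1.76-fold lower (adjusted p = 0.00998) and not well above background at 50 weeks. Car3, a carbonic anhydrase, fell by 1.94 (SE 0.204, adjusted p = 0.0148), the scavenger receptor gene Stab2 by 1.72 (SE 0.241, adjusted p = 0.035), and S100g, a calcium-binding protein gene under vitamin D control, by 1.67 (SE 0.173, adjusted p = 0.0147). Cenpf, a kinetochore gene of dividing cells, was at least 2.9-fold lower, Wfdc3 at least 3.49-fold and Npy6r at least 1.51-fold. Lockd, Ankrd35 and Otos fell and were at -1.20, -1.18 and -1.16, Otos being well above background on 1 of 2 arrays at 50 weeks. In all, 208 genes were higher and 33 lower among 22646 tested, 209 of the 241 by at least 2-fold, and 2395 genes had an unadjusted p under 0.05. Without SAMP1 10-week replicate 4 or 5 the count was 54 or 137. Without SAMP1 50-week replicate 1 or 4 it was 163 or 148, and without SAMR1 50-week replicate 6 or 12 it was 101 each. Of the 20 genes with the largest changes, 6, 11, 9 and 8 passed without those 4 SAMP1 arrays in that order, 12 without SAMR1 50-week replicate 6 or 12, and 16 without SAMR1 10-week replicate 1 or 4. Igh-VJ558, Ms4a1 and Wfdc3 passed each time.

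Immune gene groups lay higher at 50 weeks in SAMP1. Of 10 measured B and plasma cell markers, 7 rose, 0 fell and 3 did not pass, or 8 rose when adjusted over the list alone, among them Cd79b (1.85 ± 0.201, adjusted p = 0.0159). None of 9 MHC class II genes, which present antigen to T cells, passed over all genes and 9 rose when adjusted over the list alone, with a median of 0.71 and with H2-Oa at 1.21 ± 0.246, H2-DMb1 at 0.71 ± 0.143 and Cd74 at 0.58 ± 0.118. Of 17 chemokine genes 0 passed and 5 rose when adjusted over the list alone, with a median of 0.84 and with Cxcl13, which attracts B cells, at 3.74 ± 0.654 (adjusted p = 0.0724, well above background on 1 of 2 arrays at 10 weeks). Of 16 complement genes 3 rose, and 4 did when adjusted over the list alone, namely C4b (1.37 ± 0.149, adjusted p = 0.0159), C4a (1.24 ± 0.13, adjusted p = 0.0148) and C3 (1.17 ± 0.158, adjusted p = 0.0303) over all genes. The lists passed with adjusted p = 2.01e-15 for B and plasma cells, 2.09e-10 for MHC class II, 2.31e-05 for chemokines and 5.2e-05 for complement, and each had adjusted p = 0.485 with an estimated correlation. T cell markers (median 0.65, 0 of 12 passing, 4 adjusted over the list alone, adjusted p = 0.00308), NK and cytotoxic markers (median 0.56, 0 of 8 passing, 2 adjusted over the list alone, adjusted p = 0.00561) and macrophage and dendritic cell markers (median 0.21, 0 of 16 passing, 2 adjusted over the list alone, adjusted p = 0.00181) also passed as lists. These had adjusted p = 0.485, 0.485 and 0.583 with an estimated correlation, and their leading members were Cd2 at 1.87 ± 0.334, Nkg7 at 0.77 ± 0.194 and Lyz2 at 0.88 ± 0.142. The macrophage call was lost without SAMP1 50-week replicate 4 (adjusted p = 0.299) and the NK call without SAMP1 50-week replicate 1 (0.0744), and the T cell call without the filter on dim probes (0.0607). Without SAMP1 10-week replicate 5, Cd2 (adjusted p = 0.0181), Cxcl13 (0.0498) and Itgax (0.0304) passed over all genes.

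Stress and injury genes moved the same way in SAMP1. Of 21 unfolded protein and heat shock genes, 2 rose, 0 fell and 19 did not pass, or 4 rose when adjusted over the list alone, with a median of 0.56, and Hspa1a rose by 2.81 ± 0.237 beside Hspa1b (adjusted p = 0.00747). Of 17 immediate early genes, which respond fast to stimuli, 2 rose over all genes, Nr4a1 (1.99 ± 0.27, adjusted p = 0.0303) and Ier3 (0.79 ± 0.117, adjusted p = 0.0407), and 7 when adjusted over the list alone, with a median of 0.77. Among 20 senescence and secretory phenotype genes, 2 rose, Mmp3 and the cytokine gene Il1b (2.58 ± 0.301, adjusted p = 0.0185), and 7 when adjusted over the list alone, with a median of 0.53. Gdf15 stood at 1.39 ± 0.223 (adjusted p = 0.0566). Cdkn2a, which encodes the senescence marker p16, was not well above background at 10 weeks, and its difference of at least 1.97-fold did not pass (adjusted p = 0.303). The lists passed with adjusted p = 2.09e-10, 6.67e-08 and 9.49e-06, and each had adjusted p = 0.485 with an estimated correlation. Of 18 tubular injury genes 0 passed and 4 rose when adjusted over the list alone, with a median of 0.097 and with Cd44 at 1.57 ± 0.342, Timp1 at 0.95 ± 0.226 and Cdkn1a at 0.81 ± 0.18. That list passed with adjusted p = 0.00541, which became 0.596 with an estimated correlation, 0.0561 without the filter on dim probes and 0.067 with haemoglobin as a covariate. Cdkn2a passed without SAMP1 10-week replicate 4 (adjusted p = 0.0388) and Cd44 without replicate 5 (0.0198). Of 15 further genes named for this comparison that passed, 4 and 6 passed without SAMP1 10-week replicates 4 and 5, 8 and 7 without SAMP1 50-week replicates 1 and 4, 7 without SAMR1 50-week replicate 6 or 12, and 11 without SAMR1 10-week replicate 1 or 4. Azgp1, Masp2 and Slc7a12, chosen after their values were seen, passed each time.

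Cell division genes were lower at 50 weeks in SAMP1. Of 24 measured cell cycle genes, 1 fell, 0 rose and 23 did not pass, while 14 fell when adjusted over the list alone and all 24 estimates were negative, with a median of -0.50 (adjusted p = 2.09e-10, and adjusted p = 0.485 with an estimated correlation). Ccnb1, a cyclin of mitosis, fell by 0.87 (SE 0.106, adjusted p = 0.0211), and Cdc20 was at -1.17 ± 0.214 (adjusted p = 0.0833). The list of xenobiotic metabolism genes rose with 2 of 24 members passing, Cyp2a4 (0.99 ± 0.111, adjusted p = 0.0173) and Cyp2a5 (0.82 ± 0.09, adjusted p = 0.0159), and 5 rose and 2 fell when adjusted over the list alone (median 0.090, adjusted p = 0.00424, and adjusted p = 0.58 with an estimated correlation). That call was lost without the filter on dim probes (adjusted p = 0.0924). The lists for collecting duct principal cells (median -0.21, adjusted p = 0.00808, led by Hsd11b2 at -0.45 ± 0.102), endothelium (median -0.27, adjusted p = 0.00852) and fatty acid oxidation (median -0.10, adjusted p = 0.0385) fell with 0 members passing over all genes, and 2, 0 and 0 adjusted over the list alone. They had adjusted p = 0.583, 0.665 and 0.71 with an estimated correlation. The collecting duct call was lost without SAMP1 10-week replicate 5 (adjusted p = 0.161) or 50-week replicate 1 (0.126), and the endothelial call without SAMP1 50-week replicate 1 (0.213). The fatty acid oxidation call was lost without SAMR1 10-week replicate 1 or 4 (0.0648, 0.0634), SAMP1 10-week replicate 4 (0.356), or SAMP1 50-week replicate 1 or 4 (0.0809, 0.102), with the strict filter on dim probes (0.0531) and with the mean of all kept probes (0.0515).

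Red-cell genes moved beside these groups. In SAMP1 the erythroid list was higher at 50 weeks (median 1.98, 0 of 7 members passing and 0 adjusted over the list alone, adjusted p = 0.00808, and adjusted p = 0.596 with an estimated correlation), with Hba-a1, a haemoglobin alpha gene, at 2.11 ± 1.13 (adjusted p = 0.57) and Hbb-b1 at 1.98 ± 1.02. Within slide row 1 the Hba-a1 difference was -0.31 and within row 2 it was 4.52. The erythroid call was lost without SAMP1 10-week replicate 4 (0.144) or SAMP1 50-week replicate 1 (0.156). With haemoglobin level as a covariate 53 genes passed in SAMP1, 4 of the 20 largest changes among them, and the NK (0.167), endothelial (0.0652), fatty acid oxidation (0.145) and erythroid (0.763) calls were lost.

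In SAMR1, the second comparison, the antibody genes rose too. Iglv1 rose by 5.28 ± 0.711 (adjusted p = 0.0314, well above background on 1 of 2 arrays at 10 weeks), Igh-VJ558 by 5.23 ± 0.476 (adjusted p = 0.00864) and Jchain by 5.10 ± 0.645 (adjusted p = 0.0263), with Slpi at 3.79 ± 0.437 (adjusted p = 0.0184). Masp2, a serine protease of the lectin complement pathway, rose 5.37-fold (2.43 ± 0.115, adjusted p = 0.000683), and Azgp1, a secreted zinc-binding glycoprotein, rose 5.03-fold (2.33 ± 0.118, adjusted p = 0.000888). Neurog2 rose by 2.80 ± 0.393, the adhesion receptor gene Adgra1 at least 1.85-fold, the scavenger receptor gene Cd163l1 at least 2.37-fold and Cnpy1 at least 1.71-fold. Masp2 and Azgp1, looked at in SAMP1 after their values were seen, were also higher at 50 weeks there, by 1.65 ± 0.115 (adjusted p = 0.00445) and 2.75 (adjusted p = 0.000761).

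The largest falls with age in SAMR1 were in the complement protease genes C1s1 and C1s2. C1s1 (probe on chromosome 6 at 124480775 to 124480834 of mm9) fell by 6.36 (SE 0.357, adjusted p = 0.00136), at least 47.9-fold, from 0.68 ± 0.605 to -5.69 ± 0.465 (SD, n = 2). C1s2 (124574742 to 124574801) fell by 5.91 (SE 0.309, adjusted p = 0.00103), at least 49.1-fold. Akr1c18, a steroid-metabolising reductase, fell by 3.28 (SE 0.475, adjusted p = 0.041), and Ctxn3 was at -3.13 (SE 0.199, adjusted p = 0.00209). Ppbp, a platelet chemokine gene, was at least 1.44-fold lower (adjusted p = 0.0183) and Serpina6 at least 1.16-fold (adjusted p = 0.0157), and neither was well above background at 50 weeks. Ankrd35 (-1.25), the collagen gene Col3a1 (-1.12) and Tspan13 (-1.01) also fell. In all, 186 genes were higher and 31 lower, 187 of the 217 by at least 2-fold, and 2730 had an unadjusted p under 0.05. Leaving out SAMR1 10-week replicate 1 or 4 left 96 or 108 genes, and leaving out SAMR1 50-week replicate 6 or 12 left 74 or 44. Of the 20 largest changes 10 and 12 passed without those 10-week arrays, 7 without SAMR1 50-week replicate 6 or 12, 17 without SAMP1 10-week replicate 4 or 5, and 16 without SAMP1 50-week replicate 1 or 4. Cnpy1, Masp2, Cd163l1, Azgp1, C1s1, C1s2 and Ctxn3 passed each time. With normexp background correction 68.8% of 397 genes were higher, against 85.7% with the processed signal.

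Among gene groups in SAMR1, B and plasma cell markers rose with 3 of 10 members passing, 0 falling and 7 not passing, and with 7 adjusted over the list alone (median 1.14, adjusted p = 3.26e-06). Pou2af1 rose by 2.21 ± 0.246 (adjusted p = 0.0166) and was well above background on 1 of 2 arrays at 10 weeks. MHC class II genes rose with 3 of 9 passing and 8 adjusted over the list alone (median 0.79, adjusted p = 1.1e-08), among them H2-DMa (1.16 ± 0.175, adjusted p = 0.0481), H2-Ab1 (1.06 ± 0.162, adjusted p = 0.049) and Cd74 (0.83 ± 0.118, adjusted p = 0.0384). Cell cycle genes fell with 1 of 24 passing and 14 adjusted over the list alone (median -0.57, adjusted p = 7.18e-10). Ccnb1 fell by 0.84 (SE 0.106, adjusted p = 0.0271), and Pbk, a mitotic kinase gene, was at -1.51 ± 0.264. These lists each had adjusted p = 0.485 with an estimated correlation, and the cell cycle call was lost with haemoglobin as a covariate (adjusted p = 0.0595). Of the 6 genes Pou2af1, H2-DMa, H2-Ab1, Cd74, Ccnb1 and Hspa1a, 0 passed without SAMR1 10-week replicate 4 or SAMR1 50-week replicate 6 or 12. Without SAMR1 10-week replicate 1, 1 passed, and without SAMP1 10-week replicate 4 or 5 or SAMP1 50-week replicate 1 or 4, 2 did.

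Heat shock genes rose in SAMR1 with 1 of 21 passing and 2 adjusted over the list alone (median 0.34, adjusted p = 5.2e-05, and adjusted p = 0.596 with an estimated correlation), led by Hspa1a (1.57 ± 0.237, adjusted p = 0.048). Extracellular matrix and fibrosis genes fell with 1 of 26 passing and 3 adjusted over the list alone (median -0.39, adjusted p = 5.72e-05, and adjusted p = 0.58 with an estimated correlation), with Col3a1 lower and Fn1, the fibronectin gene, at -0.88 ± 0.214. Cholesterol synthesis genes fell with 0 of 21 passing (median -0.16, adjusted p = 0.023, and adjusted p = 0.612 with an estimated correlation), with Cyp51 at -0.50 ± 0.123, and macrophage markers rose with 0 of 16 passing (median 0.24, adjusted p = 0.0238, and adjusted p = 0.665 with an estimated correlation), with Lyz2 at 0.45 ± 0.142. None of either list passed when adjusted over the list alone. The complement list did not pass in SAMR1 (adjusted p = 0.265), with 3 members higher and 1, C1s1, lower. Cdkn2a was not well above background in SAMR1 at either age. The heat shock call was lost without SAMR1 50-week replicate 12 (adjusted p = 0.259), and the list's medians within slide rows 1 and 2 were -0.007 and 0.703. The cholesterol call was lost without SAMR1 10-week replicate 4 (0.094) or 50-week replicate 6 (0.217) and with the mean of all probes (0.0846), and the macrophage call without SAMR1 10-week replicate 1 (0.154), 50-week replicate 6 (0.115) or 12 (0.0547) and without the filter on dim probes (0.0853).

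Red-cell genes moved the opposite way in SAMR1, where the erythroid list fell at 50 weeks with a median of -5.15 (0 of 7 passing, 6 adjusted over the list alone, adjusted p = 4.92e-05, and adjusted p = 0.485 with an estimated correlation). Hba-a1 was at -5.37 ± 1.13 (adjusted p = 0.136) and Hbb-bt at -5.15 ± 1.07 (adjusted p = 0.131). With haemoglobin level as a covariate 13 genes passed in SAMR1, 0 of the 20 largest changes among them. C1s1 was at -7.21 in that fit, a larger fall than without the covariate, but did not pass (adjusted p = 0.0697). The cholesterol (0.93), macrophage (0.766) and erythroid (0.945) calls were lost with it. The covariate followed age in SAMR1.

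**Figure D1:**
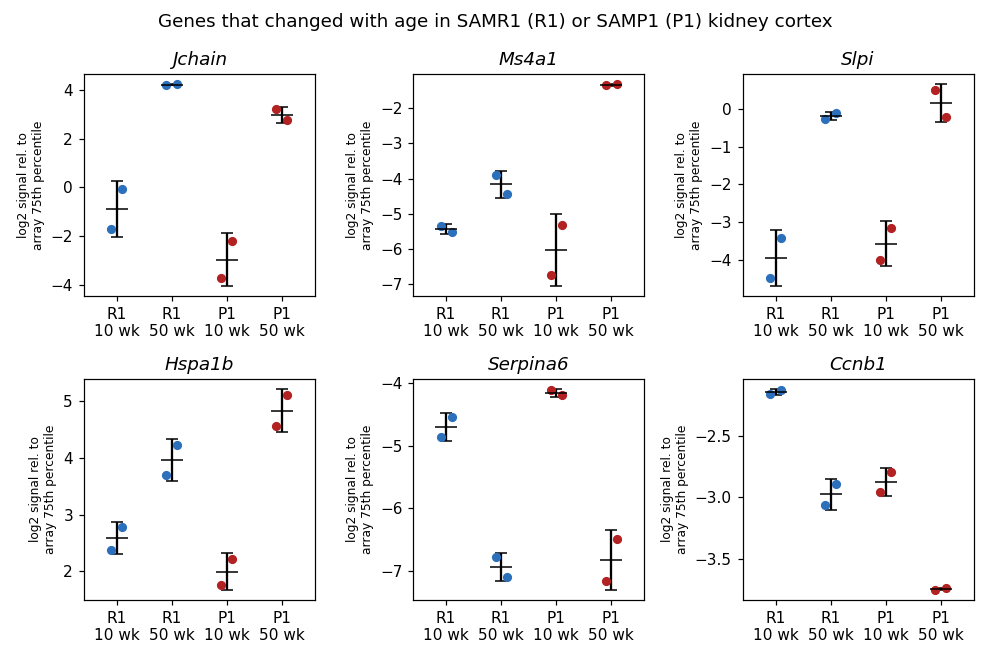
Log2 signal relative to the array's 75th percentile (vertical axis) for 6 genes in SAMR1 (R1, blue) and SAMP1 (P1, red) kidney cortex at 10 and 50 weeks, with a point per mouse (n = 2), a bar for the mean and whiskers for the SD. Jchain lies higher at 50 weeks in both strains. The Ms4a1 probe shown reaches a mean of -1.34 in SAMP1 at 50 weeks.

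The age changes of both strains overlapped. Of the genes higher at 50 weeks, 128 passed in both strains, against 1.71 given by independent lists of those sizes (1-sided Fisher's exact test, p = 1.21e-234), and of the lower genes 8 did, against 0.0452 (p = 6.25e-17). Immunoglobulin genes made up much of this. Among 149 of them, 98 were higher in SAMP1 (median 4.09, 148 of 149 positive) and 107 in SAMR1 (median 4.33, 146 positive), and 0 were lower. Among the other 22497 genes 110 and 79 were higher (2-sided Fisher's exact test, odds ratio 394 with p = 6.19e-172 in SAMP1 and 733 with p = 2.18e-203 in SAMR1). These Fisher p-values treat genes as independent trials, which they are not. Both comparisons also shared 1 spread estimate per gene from all 8 arrays, so the p-values overstate the evidence. Of the 128 shared higher genes 41 were not immunoglobulin genes, beside the 8 lower ones. When the fit and the adjustment were repeated without immunoglobulin genes, the shared changes of both directions fell to 27. Fold changes of both strains correlated across genes at r = 0.651, or 0.357 without immunoglobulin genes, where genes are not independent replicates, and the groups of both comparisons shared no array. Without SAMP1 10-week replicate 4 or 5 the 136 shared changes became 37 or 74. Without SAMR1 10-week replicate 1 or 4 they became 64 or 80, and without SAMR1 50-week replicate 6 or 12 they became 44 or 30. Ppbp was the 1 gene that passed in opposite directions, and in SAMP1, where it was looked at after its values were seen, it was at least 4-fold higher (adjusted p = 0.0293) and not well above background at 10 weeks. That call was lost without SAMP1 10-week replicate 4 or 5, SAMR1 10-week replicate 1 or 4 or SAMR1 50-week replicate 6 or 12. The call in SAMR1 was lost without any of the 4 SAMR1 arrays. Haemoglobin genes also fell in SAMR1 and rose in SAMP1, so blood stays open for this platelet gene.

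The third comparison was strain at 10 weeks. SAMP1 cortex had far higher signal for several genes that were not well above background in SAMR1. Dydc2 was higher by 8.23 ± 0.249 and at least 75.3-fold (adjusted p = 4.78e-05), and Gabra3, a subunit gene of the GABA receptor, by 6.47 ± 0.172 and at least 20-fold (adjusted p = 3.15e-05). The carboxylesterase gene Ces1g, whose product hydrolyses lipid esters, was 40.4-fold higher (5.34 ± 0.228, adjusted p = 0.000186), and Ces2h of the same family was 27.2-fold higher, being well above background on 1 of 2 SAMR1 arrays. Ifi27l2a, an interferon-induced gene, was higher by 5.04 ± 0.798 (adjusted p = 0.0247), and Cd8a, the co-receptor of cytotoxic T cells, was at least 14.1-fold higher (adjusted p = 0.00169). Elobl, Zfp971 and Mrpl35 were at least 11.5-fold, 7.8-fold and 5.31-fold higher.

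Other genes were lower in SAMP1 at 10 weeks. Fabp1, the liver-type fatty acid-binding protein, was 37.2-fold lower (-5.22 ± 0.123, adjusted p = 2.7e-05), and Mep1a, a brush border metalloprotease, was 15.8-fold lower, at 3.27 against 7.25 (-3.98 ± 0.114, adjusted p = 4.16e-05). Ctxn3 was at least 14.6-fold lower (adjusted p = 5.61e-05), Zfp33b at least 10.1-fold, Ankrd65 at least 8.58-fold and the platelet collagen receptor gene Gp6 at least 5.04-fold. Prim2, Pik3c2g and Spon1 were lower, at -4.12 ± 0.257, -3.81 ± 0.142 and -3.61 ± 0.311, and Henmt1 at least 2.84-fold. In all, 451 genes were higher and 314 lower in SAMP1, 447 of the 765 by at least 2-fold, and 3271 had an unadjusted p under 0.05. Leaving out SAMP1 10-week replicate 4 or 5 left 312 or 331 genes, and SAMR1 10-week replicate 1 or 4 left 376 or 340. Of the 20 largest differences 18 passed whichever array was left out. Ifi27l2a was lost without SAMP1 10-week replicate 4 or 5 or SAMR1 50-week replicate 6 or 12, and Henmt1 without SAMP1 10-week replicate 4 or 5.

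Interferon response genes formed the clearest group difference at 10 weeks. Of 24 measured, 15 were higher in SAMP1, 0 lower and 9 did not pass, with 21 higher when adjusted over the list alone (median 1.19, adjusted p = 4.87e-22, and adjusted p = 0.485 with an estimated correlation). Oas1a, an antiviral RNA sensor gene, was higher by 4.18 ± 0.285 (adjusted p = 0.00096), the transcription factor gene Irf7 by 2.36 ± 0.138 (adjusted p = 0.000555), Usp18 by 1.87 ± 0.107 (adjusted p = 0.000527) and Oasl1 by 1.59 ± 0.098 (adjusted p = 0.000642). T cell markers were higher with 1 of 12 passing, Cd8a, and 1 adjusted over the list alone (median 0.64, adjusted p = 0.000198, and adjusted p = 0.485 with an estimated correlation). The Cd8a probe lies on chromosome 6 (71328911 of mm9) between those of Fabp1 (71154906), lower in SAMP1, and Mrpl35 (71763258), higher. A strain difference in that stretch, apart from T cell content, stays open for Cd8a and was not tested. Whether the list passes without Cd8a was not tested either. Macrophage markers were higher with 3 of 16 passing, and 8 higher and 1 lower adjusted over the list alone (median 0.45, adjusted p = 0.000431, and adjusted p = 0.571 with an estimated correlation), namely Cd68 (0.56 ± 0.088), C1qb (0.85 ± 0.143) and C1qc (0.93 ± 0.173). Cholesterol synthesis genes were higher with 2 of 21 passing and 7 adjusted over the list alone (median 0.22, adjusted p = 0.000607, and adjusted p = 0.492 with an estimated correlation), the squalene epoxidase gene Sqle (1.18 ± 0.14, adjusted p = 0.00842) among those passing. These 4 lists passed whichever array was left out. Cd68, C1qb and C1qc lost their calls without any 1 of SAMR1 10-week replicates 1 and 4 and SAMP1 10-week replicates 4 and 5. Cd68 also lost its call without SAMP1 50-week replicate 1 or 4, C1qb and C1qc without SAMR1 50-week replicate 6 or 12, and Sqle without SAMR1 10-week replicate 1 or SAMP1 10-week replicate 4.

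Smaller shifts at 10 weeks involved intercalated cells, fibroblasts and stress genes. Intercalated cell markers (median 0.27, adjusted p = 0.00155, led by Slc4a1 at 0.46 ± 0.107) and fibroblast and mesangial markers (median 0.31, adjusted p = 0.00808, led by Dcn at 0.50 ± 0.113) were higher with 0 of 10 and 0 of 12 members passing, and with 2 and 1 adjusted over the list alone. Both had adjusted p = 0.485 with an estimated correlation. Heat shock genes (1 of 21 passing, median -0.22, adjusted p = 0.0137) were lower with Chac1, a glutathione-degrading enzyme gene of the stress response, at -1.23 ± 0.178 (adjusted p = 0.0188). Cell cycle genes were lower with 1 of 24 passing (median -0.20, adjusted p = 0.0289), namely Ccnb1 (-0.73 ± 0.106, adjusted p = 0.019). Male-biased kidney genes were lower with 1 of 12 passing (median -0.17, adjusted p = 0.024), the transporter gene Slco1a1 (-0.98 ± 0.146, adjusted p = 0.0202). Oxidative phosphorylation genes (0 of 36 passing, median -0.077, adjusted p = 0.0186) and distal convoluted tubule markers (0 of 7, median -0.16, adjusted p = 0.0387, Trpm6 at -0.57 ± 0.138) were lower. Adjusted over the list alone 1 heat shock, 1 cell cycle, 2 male-biased, 0 oxidative phosphorylation and 2 distal tubule genes were lower, and these 5 lists had adjusted p = 0.71, 0.686, 0.608, 0.837 and 0.485 with an estimated correlation. Erythroid genes were lower in SAMP1 (0 of 7 passing, 1 higher and 6 lower adjusted over the list alone, median -2.80, adjusted p = 0.024, and adjusted p = 0.646 with an estimated correlation), with Hba-a1 at -3.15 ± 1.13.

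Several of these smaller calls rested on single arrays. Without SAMP1 10-week replicate 4 the heat shock (adjusted p = 0.0864), cell cycle (0.26), distal tubule (0.26) and erythroid (0.158) calls were lost. Without SAMP1 10-week replicate 5 the fibroblast (0.0892), male-biased (0.251) and oxidative phosphorylation (0.0902) calls were lost, without SAMR1 10-week replicate 1 the cell cycle (0.232), oxidative phosphorylation (0.0847) and distal tubule (0.0729) calls, and without SAMR1 10-week replicate 4 the male-biased (0.211), erythroid (0.0878) and distal tubule (0.0736) calls. The distal tubule call was also lost without SAMR1 50-week replicate 6 (0.0516) or SAMP1 50-week replicate 1 or 4 (0.0548, 0.0558). The genes Ccnb1 and Chac1 lost their calls without SAMP1 10-week replicate 4 or 5 or SAMR1 10-week replicate 1 or 4, and Slco1a1 without SAMP1 10-week replicate 5 or SAMR1 10-week replicate 1 or 4. With haemoglobin as a covariate 184 genes passed, 18 of the 20 largest differences among them, and the intercalated cell (0.121), fibroblast (0.0871), heat shock (0.347), cell cycle (0.685), oxidative phosphorylation (0.889), erythroid (0.847) and distal tubule (0.0997) calls were lost. The strict filter on dim probes ended the cell cycle call (0.0562), and the mean of all kept probes ended the fibroblast (0.052) and distal tubule (0.0551) calls.

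The fourth comparison was strain at 50 weeks. Dydc2 was higher in SAMP1 by 7.65 ± 0.249 and at least 66-fold (adjusted p = 6.44e-05), Ces1g was 161-fold higher (7.33 ± 0.228, adjusted p = 5.21e-05), and Gabra3 was at least 20.6-fold higher. Sprr2f, a small proline-rich protein gene of epithelia, was higher by 7.10 ± 1.27 and at least 31.1-fold (adjusted p = 0.0285). C1s1 and C1s2 did not pass at 10 weeks, where they were looked at after their values were seen (0.28 ± 0.357 and 0.17 ± 0.309). They were higher in SAMP1 by 6.52 ± 0.357 (at least 53.3-fold, adjusted p = 0.000428) and 6.02 ± 0.309 (at least 53.1-fold, adjusted p = 0.000317) at 50 weeks. Their interaction did not pass (adjusted p = 0.0667 each). Ifi27l2a was higher by 5.92 ± 0.798 (adjusted p = 0.0107), and Elobl and Zfp971 at least 9.66-fold and 7.74-fold.

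Fabp1 was 46.7-fold lower in SAMP1 at 50 weeks (-5.55 ± 0.123, adjusted p = 1.94e-05) and Mep1a 14.3-fold lower (-3.84 ± 0.114, adjusted p = 4.72e-05). Zfp33b, Ankrd65 and the melanocortin receptor gene Mc3r were at least 10.4-fold, 9.3-fold and 6.94-fold lower. Lhfpl1, Shisa7, Pik3c2g and Prim2 were lower, at -4.11 ± 0.241, -3.96 ± 0.316, -3.94 ± 0.142 and -3.78 ± 0.257, and the MHC class I gene H2-Q1 was at least 2.95-fold lower. Ctxn3, looked at here after its values were seen, was at least 1.52-fold lower (adjusted p = 0.00107). In all, 728 genes were higher and 517 lower, 707 of the 1245 by at least 2-fold, and 4292 had an unadjusted p under 0.05. Leaving out SAMP1 50-week replicate 1 or 4 left 816 or 586 genes, and without replicate 1 the balance turned to 402 higher and 414 lower, and SAMR1 50-week replicate 6 or 12 left 703 or 650. Of the 20 largest differences 17 passed whichever array was left out. Sprr2f was lost without any of those 4 arrays, and Ifi27l2a and Mc3r without SAMP1 50-week replicate 4 or SAMR1 50-week replicate 6 or 12.

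Immune groups differed between the strains at 50 weeks. Interferon response genes were higher in SAMP1 with 17 of 24 passing, 0 lower and 7 not passing, and with 20 adjusted over the list alone (median 1.26, adjusted p = 4.46e-21), including Oas1a (3.83 ± 0.285), Irf7 (2.01 ± 0.138), Isg15 (1.41 ± 0.107) and Oasl1 (1.33 ± 0.098). T cell markers were higher with 6 of 12 passing and 7 adjusted over the list alone (median 1.26, adjusted p = 8.84e-07), including Cd8a (at least 9.11-fold), Cd2 (2.27 ± 0.334), Cd6 (1.42 ± 0.171) and Lck (1.11 ± 0.161). Chemokine genes were higher with 3 of 17 passing and 6 adjusted over the list alone (median 1.05, adjusted p = 3.71e-06), including Cxcl16 (1.05 ± 0.156) and Ccl6 (1.24 ± 0.236). NK and cytotoxic markers were higher with 2 of 8 passing, Nkg7 (1.97 ± 0.194) and Klrk1 (1.31 ± 0.15), and with 4 higher and 1 lower adjusted over the list alone (median 1.07, adjusted p = 0.00932). These lists each had adjusted p = 0.485 with an estimated correlation. Macrophage markers were higher with 4 of 16 passing and 8 adjusted over the list alone (median 0.57, adjusted p = 5.72e-05, and adjusted p = 0.492 with an estimated correlation), namely Lyz2, C1qc, Mrc1 and C1qb. B and plasma cell markers were higher with 3 of 10 passing, including Cd79b (1.36 ± 0.201) and Ms4a1 (2.83 ± 0.443, with another probe at -0.31, against that direction), and with 5 adjusted over the list alone (median 0.56, adjusted p = 0.0411, and adjusted p = 0.596 with an estimated correlation). Immunoglobulin genes lay the other way, with 3 of 149 higher and 20 lower in SAMP1 and a median of -0.80 (22 positive), which was looked at after the values were seen, so antibody transcripts were not higher in SAMP1 as a whole. The B cell call was lost without SAMP1 50-week replicate 1 (0.0841) or SAMR1 50-week replicate 6 (0.0988) or 12 (0.113), with quantile normalization (0.0659), normexp (0.0591) and the strict filter on dim probes (0.31), and the NK call without SAMP1 50-week replicate 1 (0.0549).

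Among other groups at 50 weeks, cholesterol synthesis genes were higher in SAMP1 with 6 of 21 passing, and with 11 higher and 1 lower adjusted over the list alone (median 0.43, adjusted p = 5.27e-06), including Sqle (1.88 ± 0.14, adjusted p = 0.00122), Insig1 (1.00 ± 0.128) and Fdft1 (0.70 ± 0.116). Immediate early genes were higher with 3 of 17 passing and 3 adjusted over the list alone (median 0.57, adjusted p = 0.000347), namely Nr4a1 (2.15 ± 0.27), Ier3 (1.47 ± 0.117) and Fosb (0.72 ± 0.135). Fibroblast and mesangial markers were higher with 1 of 12 passing, Dcn (0.72 ± 0.113), and with 4 adjusted over the list alone (median 0.33, adjusted p = 0.000915). Intercalated cell markers were higher with 0 of 10 passing in either way of adjusting (median 0.21, adjusted p = 0.0153). These lists had adjusted p = 0.485 with an estimated correlation. Extracellular matrix genes were higher with 2 of 26 passing, Postn (1.29 ± 0.189) and Vim (0.63 ± 0.12), and with 2 adjusted over the list alone (median 0.33, adjusted p = 0.00203, and adjusted p = 0.614 with an estimated correlation). Complement genes were higher as a list with 5 of 16 higher and 2 lower, and with 8 and 3 adjusted over the list alone (median 0.63, adjusted p = 0.00705, and adjusted p = 0.596 with an estimated correlation), C1s1 and C1ra (1.39 ± 0.207) being higher and C4a (-0.98 ± 0.13) lower. Oxidative phosphorylation genes were lower with 0 of 36 passing in either way of adjusting (median -0.083, adjusted p = 0.0471, and adjusted p = 0.86 with an estimated correlation). Erythroid genes were higher with 0 of 7 passing and 6 adjusted over the list alone (median 4.32, adjusted p = 6.64e-05, and adjusted p = 0.485 with an estimated correlation), with Hbb-bt at 4.38 ± 1.07 and Alas2, the haem synthesis gene of red-cell precursors, at 4.34 ± 1.11 and well above background on 1 of 2 SAMR1 arrays.

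Part of the 50-week calls was also lost when a single array was left out. Without SAMP1 50-week replicate 1 the immediate early call was lost (adjusted p = 0.0664). Without SAMP1 50-week replicate 4 the intercalated cell (0.133), extracellular matrix (0.159), complement (0.0722) and oxidative phosphorylation (0.279) calls were lost, without SAMR1 50-week replicate 6 the extracellular matrix (0.0668) and complement (0.052) calls, and without SAMR1 50-week replicate 12 the intercalated cell (0.138) and oxidative phosphorylation (0.936, turned) calls. The oxidative phosphorylation call was also lost without SAMR1 10-week replicate 1 or 4 (0.063 each) or SAMP1 10-week replicate 4 (0.0635) or 5 (0.0689) and with quantile normalization (0.163), the median over probes well above background (0.065) or the mean of all kept probes (0.112). The complement call was lost with the strict filter on dim probes (0.0531). The extracellular matrix median was 0.72 within slide row 1 and -0.028 within row 2. Of 41 further genes named at 50 weeks that passed, 28 and 20 passed without SAMP1 50-week replicates 1 and 4, 20 and 19 without SAMR1 50-week replicates 6 and 12, 35 without SAMP1 10-week replicate 4 or 5 and 37 without SAMR1 10-week replicate 1 or 4. In all 14 passed each time, among them Irf7, Oas1a, Oasl1, Isg15, Cd8a, Sqle, Ier3, Nkg7 and Klrk1. With haemoglobin as a covariate 89 genes passed, 44 higher and 45 lower, 14 of the 20 largest differences among them, and the NK (0.52), B cell (0.685), erythroid (0.685) and immediate early (0.445) calls were lost.

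**Figure D2:**
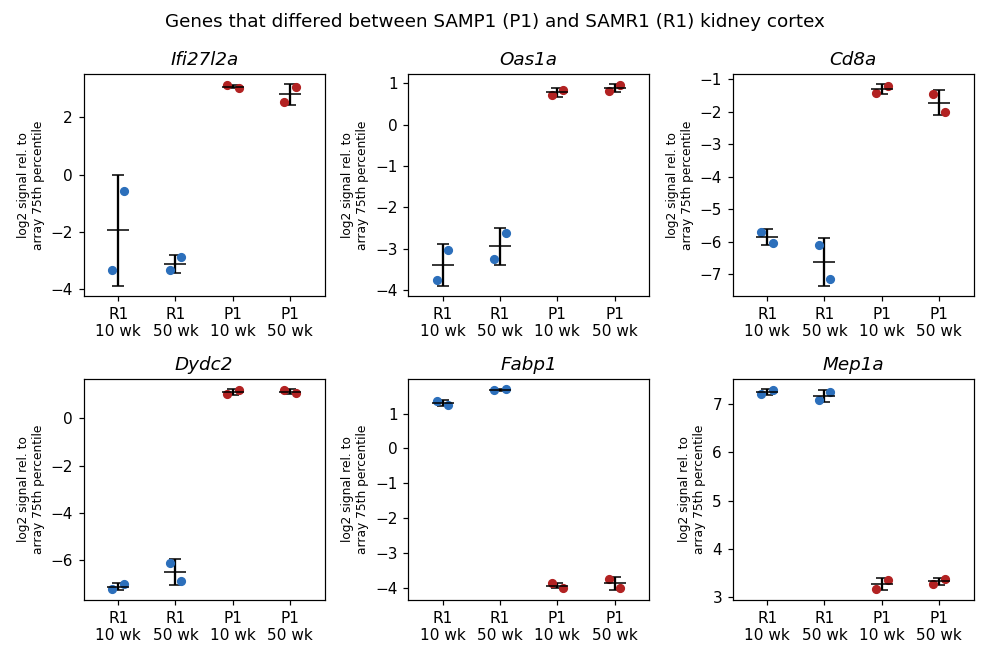
Log2 signal relative to the array's 75th percentile (vertical axis) for 6 genes in SAMR1 (R1, blue) and SAMP1 (P1, red) kidney cortex at 10 and 50 weeks, with a point per mouse (n = 2), a bar for the mean and whiskers for the SD. Dydc2 stands at 1.11 and 1.14 in SAMP1 against -7.12 and -6.51 in SAMR1, where it was not well above background, and Fabp1 and Mep1a lie lower in SAMP1 at both ages.

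The strain differences of both ages overlapped. Of genes higher in SAMP1, 362 passed at both ages against 14.5 given by independent lists, and of lower genes 253 did against 7.17, and the groups of both comparisons shared no array. Both comparisons did share 1 spread estimate per gene from all 8 arrays, so the lists are not independent. Without SAMR1 10-week replicate 1 or 4 the 615 shared differences became 321 or 312, without SAMP1 10-week replicate 4 or 5 they became 288 or 292, without SAMP1 50-week replicate 4 they became 374, and without SAMR1 50-week replicate 6 they became 409. Fold changes correlated across genes at r = 0.68, where genes are not independent replicates. The amino acid transporter gene Slc7a12, Ceacam16 and E430022K19Rik, the 3 genes that passed in opposite directions, were singled out after their values were seen. Slc7a12 was at -0.95 ± 0.169 at 10 weeks (adjusted p = 0.037) and 1.49 ± 0.169 at 50 weeks (adjusted p = 0.00586), and Ceacam16 and E430022K19Rik were at least 1.26-fold (adjusted p = 0.0141) and 1.48-fold (adjusted p = 0.0479) higher at 50 weeks. Both passed as lower at 10 weeks (adjusted p = 0.018 and 0.00812), but there Ceacam16 was not well above background in either strain and E430022K19Rik was on 1 of 2 SAMR1 arrays and 0 of 2 SAMP1 arrays, so that direction rests on signals near background. The Slc7a12 call at 10 weeks was lost without any 1 of the 8 arrays, and its call at 50 weeks was kept without each. Ceacam16 lost its call at 10 weeks without SAMR1 10-week replicate 1 or 4 or SAMP1 10-week replicate 4 or 5, and at 50 weeks without SAMP1 50-week replicate 1 or 4. E430022K19Rik lost its call at 10 weeks without SAMP1 10-week replicate 4, and at 50 weeks without SAMR1 50-week replicate 6 or 12 or any of the 4 SAMP1 arrays. Other probes of the same genes pointed the same way in 281 of 343 cases at 10 weeks (81.9%) and 436 of 517 at 50 weeks (84.3%), but 104 (30.3%) and 143 (27.7%) of them had under 0.25 of the difference or went against it, and 525 of the 765 and 871 of the 1245 genes had only 1 kept probe. Another probe of Prim2 was at 0.094 and another of Spon1 at 2.74 at 10 weeks, both against the direction given for the gene. Strain variants under the 60-base probes, which can alter a signal without a change in expression, were not looked up, so they stay open for the strain differences.

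MHC genes differed between the strains in both directions. H2-Aa, a class II gene looked at after its values were seen, was lower in SAMP1, at -3.24 ± 0.166 at 10 weeks (adjusted p = 0.000324) and -3.17 ± 0.166 at 50 weeks (adjusted p = 0.000351), while H2-DMb1 was higher by 1.24 ± 0.143 and 1.06 ± 0.143 and H2-Oa by 1.59 ± 0.246 at 50 weeks. The class II list did not pass at either age (2 of 9 higher and 1 lower at both, adjusted p = 0.0804 and 0.14). The class I genes H2-D1 and H2-K1, looked at after their values were seen, were at -2.73 and -1.36 at 10 weeks and -3.29 and -1.11 at 50 weeks. Another probe of H2-K1 was at 0.35 and 0.15, against that direction. H2-T23 (0.68 ± 0.103, adjusted p = 0.0209) and H2-Q2 (0.58 ± 0.086, adjusted p = 0.0202), class I genes picked after seeing values, were higher at 10 weeks. These did not pass at 50 weeks (0.33 and 0.11), and their calls at 10 weeks were lost without any 1 of the 4 arrays of that age. The H2-K1 call at 10 weeks and the H2-DMb1 call at 10 weeks were lost without SAMR1 10-week replicate 1 or 4. At 50 weeks H2-K1 lost its call without SAMP1 50-week replicate 1 or 4 or SAMR1 50-week replicate 12, H2-DMb1 without SAMP1 50-week replicate 4 or SAMR1 50-week replicate 6, and H2-Oa without any of those 4 arrays. The organic anion transporter gene Slco1a6 was lower in SAMP1, at -2.53 ± 0.119 and -1.98 ± 0.119 with 1 probe, while another of its probes was at 1.61 and 1.45.

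The interaction asked whether the age change differs between strains. A single gene passed, with 1448 at an unadjusted p under 0.05. It is an immunoglobulin kappa variable segment (probe on chromosome 6 at 70384946 to 70385004 of mm9), named after its values were seen, which was at 0.13 with age in SAMP1 and 5.66 in SAMR1 (difference -5.52 ± 0.14, adjusted p = 0.000173) and was well above background only in SAMR1 at 50 weeks. The size of this difference and its standard error thus depend on signals near background. The segment lay at -7.367 and -7.235 in SAMP1, and a strain variant under its probe stays open. The 5 higher and 5 lower named genes with the smallest p did not pass. C1s1 and C1s2 differed by 6.24 ± 0.505 and 5.85 ± 0.436, Ppbp by 5.27 ± 0.461, Ctxn3 by 3.36 ± 0.281 and Cnpy1 by -3.03 ± 0.258, each with adjusted p = 0.0667. Slc7a12, which was higher at 50 weeks in SAMP1 (2.35 ± 0.169, adjusted p = 0.00494), differed by 2.44 ± 0.239 (adjusted p = 0.1), Car3 by -2.35 ± 0.288 (adjusted p = 0.197), and Ccr10, Olfr1466 and Tas2r113 by -1.17, -1.61 and -1.13. C1s1 and C1s2 were not well above background in SAMR1 at 50 weeks, Ppbp in SAMR1 at 50 weeks and SAMP1 at 10 weeks, Ctxn3 in SAMP1 at either age, Cnpy1 in any group but SAMR1 at 50 weeks, and Ccr10 in SAMR1 at 10 weeks. The sizes of these differences therefore depend on signals near background. Without SAMP1 10-week replicate 5, SAMP1 50-week replicate 1 or 4, or SAMR1 50-week replicate 6 or 12 the count was 3, 9, 2, 3 and 2, with C1s2 and Ppbp passing without SAMP1 50-week replicate 1, Ppbp without replicate 4, and Cnpy1 without SAMP1 10-week replicate 5.

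As groups, 13 lists moved up with age in SAMP1 relative to SAMR1, with 0 members passing over all genes in any of them. Erythroid genes differed most (median 7.06, 6 of 7 adjusted over the list alone, adjusted p = 8.7e-08, and adjusted p = 0.485 with an estimated correlation), with Hba-a1 at 7.48 ± 1.6 and Hba-a2 at 7.50 ± 1.59. B and plasma cell markers followed (median 0.90, 3 of 10 adjusted over the list alone, adjusted p = 4.15e-05, 0.485 with an estimated correlation). Ms4a1, not well above background at 10 weeks in either strain, was at 3.42 ± 0.626. Another of its probes lacked the strain difference at 50 weeks. The 149 immunoglobulin genes did not rise more in SAMP1 (median age change 4.09, against 4.33 in SAMR1). The 1 that passed in the interaction went the other way. Chemokines (median 0.56, 1 of 17, adjusted p = 0.000494), immediate early genes (median 0.32, 3 of 17, adjusted p = 0.000811, Fosb at 1.21 ± 0.191), senescence genes (median 0.22, 2 of 20, adjusted p = 0.00185, Il1b at 2.89 ± 0.426 and Mmp3, well above background only in SAMP1 at 50 weeks, at 4.03 ± 0.588), cholesterol synthesis genes (median 0.18, 0 of 21, adjusted p = 0.005), T cell markers (median 0.61, 3 of 12, adjusted p = 0.00541, Cd2 at 1.73 ± 0.472 and Lck at 0.88 ± 0.228) and female-biased kidney genes (median 0.50, 1 of 8, adjusted p = 0.00561, led by Slc7a12) passed as lists, the counts being adjusted over the list alone. These 6 lists had adjusted p = 0.516, 0.492, 0.516, 0.583, 0.492 and 0.485 with an estimated correlation. Heat shock genes (median 0.27, adjusted p = 0.0117), xenobiotic metabolism genes (median 0.072, 0.0207), complement genes (median 0.087, 0.0221, C3 at 0.87 ± 0.223), extracellular matrix genes (median 0.14, 0.0237, Postn at 1.22 ± 0.267) and tubular injury genes (median 0.19, 0.0487, Cd44 at 1.63 ± 0.484) passed with 3 complement genes and 0 of the others adjusted over the list alone. With an estimated correlation they had adjusted p = 0.71, 0.596, 0.633, 0.71 and 0.668.

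Of these 13 calls, those of erythroid, B cell, chemokine and female-biased genes held whichever array was left out. Without SAMR1 50-week replicate 6 the cholesterol (adjusted p = 0.0852), complement (0.145), extracellular matrix (0.273), tubular injury (0.426), heat shock (0.695, turned) and xenobiotic (0.186) calls were lost, and without replicate 12 the T cell call (0.196). Without SAMP1 50-week replicate 1 the immediate early (0.256) and xenobiotic (0.0603) calls were lost, and without replicate 4 the complement (0.475), extracellular matrix (0.54), senescence (0.0558), tubular injury (0.157) and heat shock (0.201) calls. Without SAMR1 10-week replicate 1 the extracellular matrix (0.319) and xenobiotic (0.13) calls were lost, without replicate 4 the senescence (0.0917) and tubular injury (0.687) calls, without SAMP1 10-week replicate 4 the tubular injury call (0.0589), and without replicate 5 the extracellular matrix (0.0521) and xenobiotic (0.149) calls. The strict filter on dim probes ended the complement (0.212) and tubular injury (0.0705) calls, normexp the extracellular matrix call (0.0503), and the mean of all kept probes the cholesterol call (0.114). Quantile normalization (0.0821), the median over probes well above background (0.0605), the slide row as a block (0.059) and the deposited value table (0.0505) also ended the tubular injury call. With haemoglobin as a covariate 2 of the 13 lists passed, complement and extracellular matrix (0.0106 each). Within slide rows 1 and 2 the medians were 0.685 and -0.189 for extracellular matrix, 0.205 and -0.165 for complement and 0.625 and -0.212 for heat shock genes.

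Haemoglobin transcripts differed widely between arrays. The mean log2 level of the haemoglobin genes and Alas2 was 4.78 and 5.27 in SAMR1 at 10 weeks, -1.13 and 0.85 in SAMR1 at 50 weeks, 0.95 and 3.33 in SAMP1 at 10 weeks, and 5.25 and 2.99 in SAMP1 at 50 weeks. Hba-a1 had group means of 8.05, 2.68, 4.90 and 7.01 in that order. Much of this spread lay between groups. Haemoglobin level as a covariate is thus hard to tell apart from age in SAMR1, strain at 50 weeks and the interaction. Calls lost with the covariate do not show that blood explains a change. The complement gene C1ra, whose probe lies beside C1s1 on chromosome 6, was at -1.15 with age in SAMR1 (adjusted p = 0.0866, not passing) and -0.006 in SAMP1.

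**Figure D3:**
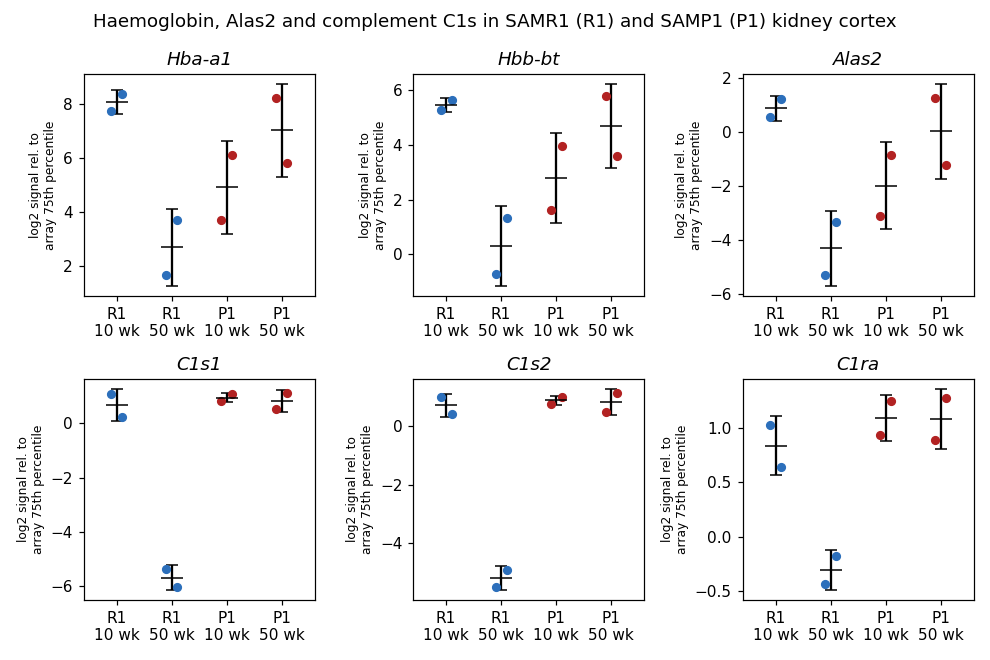
Log2 signal relative to the array's 75th percentile (vertical axis) for haemoglobin genes, Alas2 and complement genes in SAMR1 (R1, blue) and SAMP1 (P1, red) kidney cortex at 10 and 50 weeks, with a point per mouse (n = 2), a bar for the mean and whiskers for the SD. Hba-a1, Hbb-bt and Alas2 share 1 pattern over the groups, and C1s1 and C1s2 lie near -5.69 and -5.20 in SAMR1 at 50 weeks only.

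Klotho and vitamin D genes were also examined. Kl, the klotho gene, whose loss shortens life in mice, was looked at after its values were seen and stood at -0.14 ± 0.136 with age in SAMP1 (adjusted p = 0.752) and -0.23 ± 0.136 in SAMR1 (adjusted p = 0.564). The list of klotho, phosphate and vitamin D genes did not pass in any contrast (smallest adjusted p = 0.0911), but Cyp27b1, the vitamin D activating enzyme gene, was lower in SAMP1, at -1.60 ± 0.239 at 10 weeks (adjusted p = 0.0205) and -1.89 ± 0.239 at 50 weeks (adjusted p = 0.0085). The vitamin D receptor gene Vdr was at -1.02 ± 0.165 (adjusted p = 0.0266) and -1.16 ± 0.165 (adjusted p = 0.013). Another probe of Vdr was at 0.075 at 10 weeks, against that direction. At 10 weeks both calls were lost without SAMR1 10-week replicate 1 or 4 or SAMP1 10-week replicate 4 or 5, and that of Vdr also without SAMP1 50-week replicate 1 or 4. At 50 weeks both were lost without SAMR1 50-week replicate 12, and that of Vdr without SAMP1 50-week replicate 4. Podocyte (smallest adjusted p = 0.0786), proximal tubule (0.931), thick ascending limb (0.138), neutrophil (0.22), acute phase (0.127), antioxidant (0.0691), circadian clock (0.127), renin-angiotensin-aldosterone (0.106) and apolipoprotein and amyloid (0.0576) lists did not pass in any contrast.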

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

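The tests of cross-hybridisation and of a genome stretch for C1s1 and C1s2 were chosen before their results were seen, and the other tests given here only after. These results stood out because the age change differed between the strains in a test of the difference itself. For the immunoglobulin kappa variable segment the SAMP1 age change minus the SAMR1 age change was -5.52. Signal was well above background only in SAMR1 at 50 weeks, so a strain variant under the probe stays open. For the lists the median difference was 7.06 for erythroid, 0.90 for B and plasma cell, 0.61 for T cell, 0.56 for chemokine, 0.50 for female-biased, 0.32 for immediate early, 0.27 for heat shock, 0.22 for senescence, 0.19 for tubular injury, 0.18 for cholesterol synthesis, 0.14 for extracellular matrix, 0.087 for complement and 0.072 for xenobiotic metabolism genes. Each list had adjusted p of 0.485 or more with an estimated correlation.

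The haemoglobin pattern may come from differing amounts of residual blood in the pieces of cortex. The red-cell genes kept 1 ratio, since the largest SD over the 8 arrays was 0.194 after removing their mean, against raw SDs of 2.2 to 2.46. Neutrophil and platelet genes left this open, with a median correlation of 0.622 with the haemoglobin level over 8 arrays. S100a8 had r = 0.72 (permutation p = 0.0321, adjusted p = 0.0962) and rho = 0.548 (permutation p = 0.171), S100a9 r = 0.622 (permutation p = 0.103) and Pf4 r = 0.35 (permutation p = 0.386), and without the 2 farthest arrays r was 0.00944, 0.000756 and -0.734, so the relation rests on those arrays. A difference in red-cell content that belongs to age or strain stays open, as untested.

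Immunoglobulin genes were higher at 50 weeks in both strains. A differing amount of residual blood as their source is argued against in SAMR1, where they had a median of 4.33 with age while the red-cell genes had -5.18. In SAMP1 both rose, with medians of 4.09 and 1.99, but with the haemoglobin level as a covariate the immunoglobulin median was 3.74 (quartiles 2.40 and 4.55, before 2.74 and 5.20), and within slide row 1, where the red-cell genes were at -0.32, it was 3.59 with 148 of 149 positive. This argues against blood as the whole cause there too. With the covariate 35 immunoglobulin genes passed instead of 98, as their median standard error rose from 0.487 to 0.515, the fit lost 1 degree of freedom and the changes were smaller. More of these cells within the blood of older mice was not tested. Binding of 1 transcript to many probes stays open in both strains. In SAMP1 9 B and plasma cell markers that are not immunoglobulin genes had a median of 1.85 with 6 of 9 passing, so the rise there was not confined to immunoglobulin probes. In SAMR1 the same markers had a median of 1.00 with 2 of 9 passing. These markers cannot decide the question, since cells that make 1 such transcript would raise them too. Place on the slide followed age, but 13577 other genes at the same level had a median of -0.0273 and 10 spike-in probes lay between -0.0303 and 0.234. More B and plasma cells in older cortex stay open as a candidate explanation, which remains a hypothesis found and tested on the same arrays.

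C1s1 and C1s2 were low on both SAMR1 arrays of 50 weeks. SAMP1 tissue under a SAMR1 label could not give these low signals, since both genes were well above background in SAMP1 at both ages. There C1s1 was at 0.956 and 0.827 and C1s2 at 0.88 and 0.825. Of the 765 strain genes of 10 weeks, 8.5% lay nearer to SAMP1 on the SAMR1 arrays of 50 weeks, which also argues against such a label error. Binding of 1 transcript to both probes stays open. The probes had 39 mismatches in their best alignment without gaps, which was wrongly set beforehand as excluding it, since 1 transcript can hold a site for each, and on the 6 arrays where both were well above background their difference had an SD of 0.108. A differing stretch of the genome around them stays open. In limma 0 of 158 other genes within 5 Mb passed, but the rate elsewhere gives 0.753, so that none passes is a likely outcome either way (exact p of none = 0.47), and a count of 0 was wrongly set beforehand as excluding it. The neighbouring C1ra went the same way, at -1.47 and -0.82 within slide rows 1 and 2 with age in SAMR1 against -0.006 in SAMP1, but its change in SAMR1 did not pass (adjusted p = 0.0866). It passed between the strains at 50 weeks (1.39 ± 0.207), and that call was lost without SAMP1 50-week replicate 4 or SAMR1 50-week replicate 6 or 12. A variant carried by the older SAMR1 mice at or near these genes may explain the pattern and was not tested, and an effect of age stays open, as untested.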

How the results depend on the processing

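No paired analysis was possible because the compared groups share at most 1 animal number and the numbers name different animals. Where a left-out array leaves 1 array in its group, that array is assumed to vary like the other groups. Of 1216 list values under alternatives 966 kept direction and side of the threshold, 244 lost the call and 6 reversed. Of 3803 values of named genes and the other largest changes 3098 kept both, 655 lost the call, 38 gained it and 12 reversed, and of 38 values of other probes 25 kept both, 5 lost the call and 8 reversed. The deposited value table kept all 228 of these gene values. With arrays left out in turn the counts ranged over 54 to 188 for age in SAMP1, 44 to 194 for age in SAMR1, 312 to 685 and 586 to 1024 for strain at 10 and 50 weeks, 1 to 9 for the interaction, 57 to 73 for list shifts, 30 to 104 for shared age changes and 288 to 419 for shared strain differences. For age in SAMP1 the 241 genes became 147 with no filter on dim probes, 117 with probes well above background on all arrays, 38 with only the arrays of both groups, 53 with the haemoglobin covariate, 80 without immunoglobulin genes and 392 at adjusted p under 0.10. For age in SAMR1 the 217 genes became 129 with no filter, 80 with probes well above on all arrays, 397 with normexp (273 higher and 124 lower), 397 with trend and robust eBayes, 13 with the covariate, 52 without immunoglobulin genes and 365 at adjusted p under 0.10. For strain at 10 weeks the 765 genes became 499 with only the arrays of both groups, 1153 with trend and robust eBayes, 184 with the covariate, 1165 at adjusted p under 0.10 and 447 with a fold of at least 2. For strain at 50 weeks the 1245 genes became 807 with no filter, 694 with only the arrays of both groups, 89 with the covariate, 1897 at adjusted p under 0.10 and 707 with a fold of at least 2. The interaction count of 1 became 17 with normexp (9 higher and 8 lower), 2 with the mean of all kept probes, 15 with trend and robust eBayes, 2 with the slide row as a block and 7 at adjusted p under 0.10. It was 0 in limma with probes well above on all arrays (1260 at an unadjusted p under 0.05) and 0 with the covariate (874). The 64 list shifts became 0 with an estimated correlation and 8 with fry, which kept 6 of the 64. Shared age changes became 63 with no filter, 46 with probes well above on all arrays and 27 without immunoglobulin genes, and shared strain differences 398 with no filter. The covariate leaves 1 degree of freedom fewer and is hard to tell apart from several contrasts. It averages red-cell genes, so losses and reversals of the erythroid list, Alas2 and Hba-a1 with it say nothing about these genes. With it the list adjusted p of reversed lists was 0.847 for erythroid genes at 10 weeks and 0.763, 0.822 and 0.943 for immediate early, tubular injury and heat shock genes in the interaction. Genes that reversed with it were Cdkn2a (-0.57) and Kl (0.27) for age in SAMR1, C1s1 for age in SAMP1 (0.20) and strain at 10 weeks (-0.19), and Alas2 (-0.015) and Hba-a1 (-0.10) at 50 weeks. Heat shock genes reversed in the interaction without SAMR1 50-week replicate 6 (adjusted p = 0.695, range 1.59e-07 to 0.695 over arrays left out) and oxidative phosphorylation genes at 50 weeks without SAMR1 50-week replicate 12 (0.936, range 3.59e-05 to 0.936). For age in SAMP1, C1s1 (0.15) and C1s2 (0.27) reversed without SAMP1 50-week replicate 1, and C1s2 (0.063) and Kl (0.004) without SAMP1 10-week replicate 5, with lowest values of -0.41, -0.38 and -0.28 for C1s1, C1s2 and Kl. At 10 weeks C1s1 (-0.15) and C1s2 (-0.11) reversed without SAMR1 10-week replicate 4, with highest values of 0.71 and 0.45. Other probes reversed for Prim2 (0.094), Spon1 (2.74), H2-K1 (0.35), Vdr (0.075) and Slco1a6 (1.61) at 10 weeks and for Ms4a1 (-0.31), H2-K1 (0.15) and Slco1a6 (1.45) at 50 weeks. Fewer genes tested, fewer arrays or another threshold explain part of these changes by construction, and for the rest the cause was not tested. Probes near background give only bounds.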
